A study of Mus musculus with 8 samples.

How the data were processed

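Total RNA from the ileum of 4 wild-type and 4 Slc51a knockout male mice was extracted with Trizol and cleaned on a column, and 250 ng was labelled by a 3' in vitro transcription kit for Affymetrix GeneAtlas arrays, per the labels' protocols. The samples are numbered as biological replicates in the labels. The values used are the authors' deposited log2 probe set signals, normalised with RMA per the submitters' processing notes; the RMA software and its version were not given in the sources used here. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a probe set, so low signals are compressed toward a floor and a fold change near it is understated. The range of about 2.7 to 13.4 on every array and the near-equal medians are those of log2 values. The table gives no detection calls, so an expressed and an unexpressed transcript were not separated. The array strip and scan date of each sample were not given in the sources used here, and a batch that runs with genotype could not be tested. The number of arrays, 4 per genotype, limits the precision.

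The table held 45141 probe sets, of which 104 were controls. Of the other 45037, 28898 had 1 gene symbol in the platform annotation, 551 had several and 15588 had none listed; 28689 of those with 1 symbol were matched by Entrez identifier to RefSeq of mouse assembly GRCm38.p6 to update the symbol, and the rest kept the platform's symbol. Gene positions in it served only to find which tested genes neighbour Slc51a. A gene was represented by the probe set with exactly 1 symbol and the highest mean over all 8 arrays, which gave 17097 genes, with no filter on dim probe sets. Among the 150 named genes, 51 had other probe sets, 37 of these had another called in the same direction and 0 one called in the opposite direction. For 14 named genes the probe set identifier marks possible binding to other transcripts, Slc51a and H2-Aa among them. Where the deleted part of Slc51a lies relative to its probe set was not given in the sources used here.

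Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior), 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 35 lists with at least 5 measured members. The design, the lists, the named-gene rule and the alternatives were fixed before the data were examined, except where stated. The lists covered bile acid transport and FXR, NRF2 and glutathione, NADPH oxidase, xenobiotic enzymes, cholesterol synthesis, lipid absorption, fatty acid oxidation, oxidative phosphorylation, cell cycle, stem cells, mature enterocytes, proximal intestine, goblet, Paneth, enteroendocrine and tuft cells, T lymphocytes, B lymphocytes and plasma cells, myeloid cells, inflammation, antimicrobial genes, interferon, MHC class II, smooth muscle, fibroblasts and matrix, enteric neurons and glia, endothelium, adipocytes, pancreatic acini, endoplasmic reticulum stress, p53 and apoptosis, immediate early genes, heat shock, circadian genes and tight junctions. Of 652 listed genes 571 were measured under a single symbol, and the others were not analysed here.

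Named genes were Slc51a and Slc51b, 5 bile acid genes whatever their values, the 10 largest rises and 10 largest falls among genes past the threshold with non-overlapping groups and a brighter group at or above the median probe set, and up to 4 members of each list with the smallest adjusted p among those past the threshold. Other genes are named only where stated, after their values were seen. Single quality measures were compared with 2-sided exact permutation tests. On simulated data for the knockout minus wild type comparison of 17097 genes, 30% of genes changed by 0.25 on the log2 scale were recovered. The share was 82% at 0.5 and 100% at 1 and at 2, with 6 false calls. Of lists of random genes, 5 of 5 shifted and 0 of 5 unshifted were called. The simulated genes varied independently, so this does not test camera on correlated lists. The MHC class II list had an estimated correlation of 0.73. Only 50 genes were changed at each size, against 5134 called in the data.

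Alternatives were a filter on dim genes, quantile, median and cyclic loess normalisation of the deposited values, the mean of a gene's probe sets, all probe sets, eBayes with trend and robust, array weights, the replicate number as a block, leaving out each array, thresholds of 0.01 and 0.1, a fold of at least 1.5, an unmoderated equal-variance test, an estimated correlation and fry. After the data were seen, a fit without the 3 arrays with the lowest hybridization controls (wild type 2, knockout 3 and knockout 4) and a fit with these controls as a covariate were added. Figures were drawn with matplotlib 3.10.9.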

Results

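Transcript levels were measured in the ileum of adult male mice on a C57BL/6 background, 4 wild-type samples and 4 samples from mice in which Slc51a is inactivated. Slc51a encodes the alpha subunit of OST, the heteromeric transporter that moves bile acids out of the enterocyte across its basolateral membrane, and Slc51b encodes the other subunit. The mice were about 2 months old and had been fasted for 4 h. Each sample was run on 1 Affymetrix 3' expression array, and the values are normalised log2 signals, in which a difference of 1 is a doubling. The medians of the 8 arrays lay between 4.56 and 4.60. Pearson correlations across probe sets were 0.996 to 0.998 between samples of the same genotype and 0.988 to 0.992 between genotypes. The comparison asked which ileal transcripts differ when this transporter is missing. All differences below are knockout minus wild type with their standard error (SE), n = 4 per genotype, and adjusted p values come from limma.

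The Slc51a transcript was at 11.36, 11.41, 11.29 and 11.37 in the wild-type samples and at 4.67, 4.50, 4.68 and 4.56 in the knockout samples. It fell by 6.75 on the log2 scale (SE 0.05, adjusted p = 4.86e-14). Its level was 11.36 ± 0.05 (SD, n = 4) in wild type and 4.60 ± 0.09 in the knockout, where it lay near the median of all probe sets, 4.58. Slc51b fell by 0.36 (SE 0.07, adjusted p = 0.00227). Slc10a2, the apical sodium-dependent bile acid transporter, fell by 0.45 (SE 0.07), and Abcg2, an apical efflux transporter, fell by 0.62 (SE 0.06). Abcc3, a basolateral efflux transporter of conjugated organic anions, rose by 0.57 (SE 0.08, adjusted p = 0.000257). Fabp6, the ileal bile acid binding protein, was at 13.11 ± 0.02 in wild type and 13.18 ± 0.03 in the knockout, a difference of 0.07 (adjusted p = 0.217) with groups that did not overlap. The highest signals of the knockout arrays were 13.225 to 13.292, so Fabp6 lay near the top of the scale and a rise may be understated. The Fabp6 difference passed with eBayes trend and robust (adjusted p = 0.0273) and was -0.03 with cyclic loess normalisation (adjusted p = 0.644). Fgf15, the hormone that the ileum releases in response to bile acids, was at 7.13 ± 0.75 and 7.68 ± 0.58, a difference of 0.54 (SE 0.36, adjusted p = 0.305). On leaving out 1 array the Fgf15 difference ran from 0.29 without wild type replicate 3 (adjusted p = 0.618) to 0.89 without wild type replicate 4 (adjusted p = 0.0410). Nr0b2, a nuclear receptor induced by FXR, differed by 0.24 (SE 0.11, adjusted p = 0.134), with a range on leaving out 1 array from 0.13 without knockout replicate 1 (adjusted p = 0.285) to 0.34 without knockout replicate 4 (adjusted p = 0.0194). Nr0b2 lay at 4.77 in wild type and 5.01 in the knockout, near the median of all probe sets, so its difference may be understated. Of the 15 measured genes of bile acid transport and FXR signalling other than Slc51a, 1 rose, 3 fell and 11 did not pass, and the counts were the same when adjusted over the list alone, 1 and 3. The list was not called by camera (adjusted p = 0.484), its median being 0.01 and its mean -0.003 in the direction of the test.

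**Figure D1:**
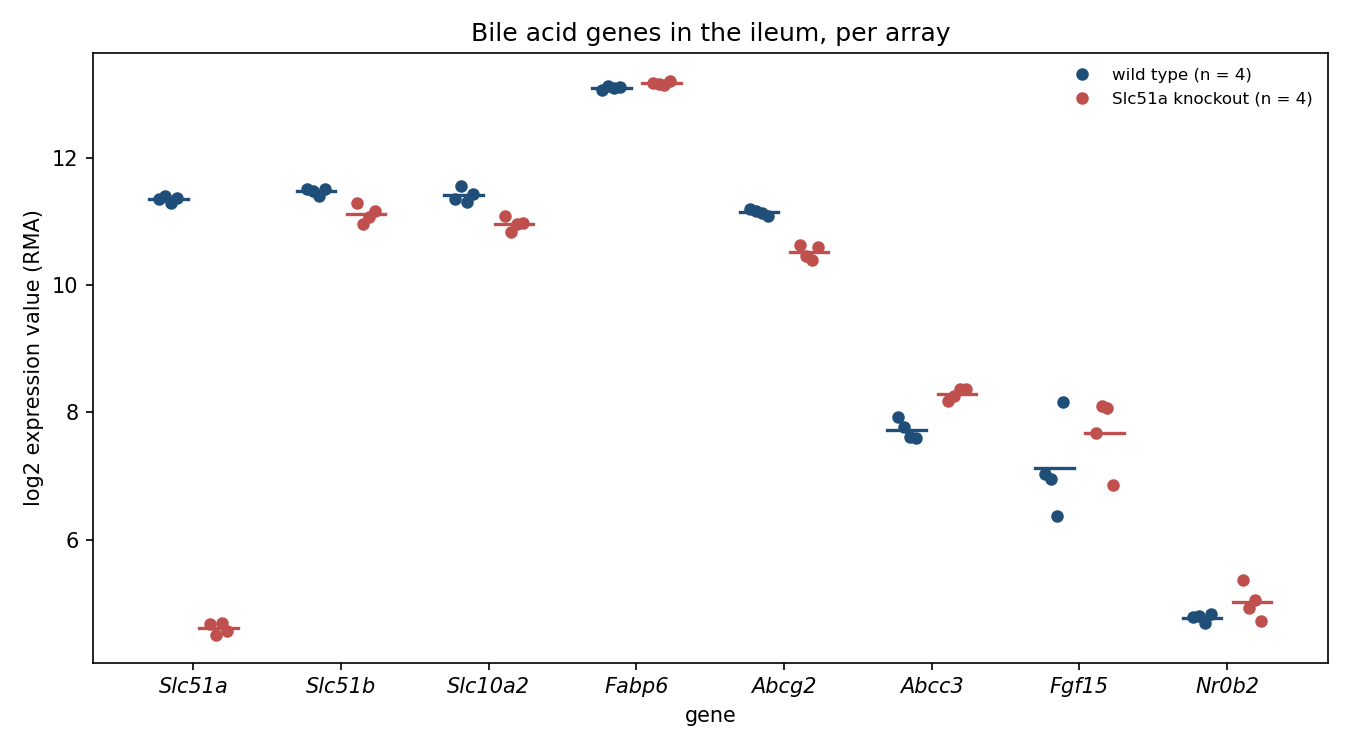
Log2 expression value (RMA) of 8 bile acid genes on each array, with wild type (n = 4) in blue and Slc51a knockout (n = 4) in red; points are arrays and lines are group means. Slc51a lies at 11.36 in wild type and 4.60 in the knockout, and the Fgf15 values of the genotypes overlap.

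Across 17097 genes, 5134 differed between the genotypes, 2924 higher and 2210 lower in the knockout. Of these, 351 rose and 474 fell by at least 1.5-fold, and 44 rose and 146 fell by at least 2-fold. The largest rises among genes whose samples did not overlap were in enzymes of glutathione conjugation and carbonyl reduction. Gsta2 rose by 2.95 (SE 0.12), Akr1b8 by 2.58 (SE 0.14), Gstm3 by 2.40 (SE 0.23), Akr1c19 by 2.08 (SE 0.08) and Gsta4 by 1.99 (SE 0.07). Aadac, an esterase, rose by 1.88, the cytokine Il18 by 1.86, Pir by 1.78, the myosin light chain Myl7 by 1.77 and the acyltransferase Mboat1 by 1.76. After Slc51a, the largest falls were in the ubiquitin-like gene Ubd, which changed by -4.44 (SE 0.29), the nucleoside transporter Slc28a2 by -4.05 (SE 0.17) and the cytochrome Cyp3a11 by -3.81 (SE 0.41). Gcnt1, a glycosyltransferase, changed by -3.48, the lactate transporter Slc5a12 by -3.27, Cyp4v3 by -3.22, ccdc198 by -3.16, the granzyme Gzma by -2.90 and H2-DMb1 by -2.84. In the knockout Ubd, Gcnt1 and Slc5a12 lay at 4.55, 4.53 and 4.16, below the median of all probe sets, 4.58. Their falls may be understated, so the order of the falls is not settled. Groups did not overlap for 5256 genes, 30.7% of those tested, where chance gives 2.86%. Without the 3 arrays whose hybridization controls were lowest, a choice made after the data were seen, 3493 genes differed, 2079 higher and 1414 lower.

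Genes of the NRF2 pathway and glutathione metabolism rose as a group. Of 26 measured members, 18 rose, 2 fell and 6 did not pass, with 20 and 3 adjusted over the list alone, and their median difference was 0.45 (camera adjusted p = 8.58e-09, adjusted p = 0.102 with an estimated correlation). Besides Gsta4, Gsta2 and Akr1b8, the glutathione reductase Gsr rose by 1.09 (SE 0.05). The members that fell, named after their values were seen, were the catalase gene Cat (-0.72) and the epoxide hydrolase Ephx1 (-0.42). The list of xenobiotic enzymes and transporters was not called (adjusted p = 0.0669, median -0.09), with 4 of 20 members higher, 7 lower and 9 not passing, and 4 and 8 adjusted over the list alone. It was called lower with quantile normalisation (adjusted p = 0.0359), median centring (0.0433), cyclic loess (0.0285), the mean of probe sets (0.0451) and fry (0.0235). It was also called without wild type replicate 1 (adjusted p = 0.0355) and without knockout replicate 2 (0.0418). In it Cyp3a11 fell as given above, Cyp3a25 changed by -1.48 (SE 0.24) and the sulfotransferase Sult1b1 by -0.64, whereas the carboxylesterase Ces1f rose by 1.00 (SE 0.11). In the same samples 13 of 13 smooth muscle, 17 of 19 T lymphocyte and 18 of 20 mature enterocyte genes fell.

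Transcripts of the mitochondrial respiratory chain rose by small amounts in nearly every member. Of 31 genes of oxidative phosphorylation, 27 rose, 0 fell and 4 did not pass, and 27 rose adjusted over the list alone (median 0.32, camera adjusted p = 6.06e-13, adjusted p = 0.102 with an estimated correlation). The complex I genes Ndufa5, Ndufs1, Ndufs3 and Ndufa4 rose by 0.84, 0.56, 0.52 and 0.46. Of 29 cell cycle genes, 24 rose, 0 fell and 5 did not pass, with 26 higher adjusted over the list alone (median 0.46, camera adjusted p = 2.61e-11, adjusted p = 0.200 with an estimated correlation). Among them the mitotic genes Bub1, Birc5 and Ccnb2 rose by 0.84, 0.79 and 0.68, and the thymidylate synthase Tyms by 0.66. Of 19 genes of fatty acid oxidation, 9 rose, 3 fell and 7 did not pass, with the same 9 and 3 adjusted over the list alone (median 0.32, camera adjusted p = 0.042, adjusted p = 0.416 with an estimated correlation). Acadl, Cpt2 and Cpt1a rose by 0.66, 0.65 and 0.46, and the pantetheinase Vnn1 fell by 1.31. The other members that ran against this list, named after their values were seen, were Creb3l3 (-0.75) and Acot12, the latter below the median of all probe sets in both genotypes. The call of that list was lost without wild type replicate 4 (adjusted p = 0.0599), without knockout replicate 1 (adjusted p = 0.0527) and without knockout replicate 4 (adjusted p = 0.069). It was also lost without dim genes (adjusted p = 0.0558), with quantile normalisation (0.0833), median centring (0.0571) and cyclic loess (0.0798), without the 3 arrays (0.0617) and with the hybridization controls as a covariate (0.0576). Smooth muscle and T lymphocyte genes fell in the same samples, as given further on.

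Genes of the mature enterocyte fell together. Of 20 measured members, 0 rose, 18 fell and 2 did not pass, the count being also 18 adjusted over the list alone (median -0.48, camera adjusted p = 4.93e-13, adjusted p = 0.102 with an estimated correlation). The brush border peptidases Mep1a, Xpnpep2, Anpep and Dpp4 changed by -1.28, -1.16, -0.87 and -0.73. Of 11 genes more abundant in the proximal intestine, 1 rose, 7 fell and 3 did not pass, with 1 and 8 adjusted over the list alone (median -0.59, camera adjusted p = 0.000414, adjusted p = 0.151 with an estimated correlation). The adenosine deaminase Ada changed by -2.74 (SE 0.12), Dnase1 by -1.31 and the cholesterol transporter Npc1l1 by -0.71. The fatty acid binding protein Fabp1, named after its value was seen, rose by 0.76. Of 22 genes of lipid absorption, 3 rose, 10 fell and 9 did not pass, with 3 and 10 adjusted over the list alone (median -0.10, camera adjusted p = 0.0069, adjusted p = 0.434 with an estimated correlation). The apolipoproteins moved in both directions, Apoc3 by -1.77 and Apoa1 by -0.73 against Apoc2 by 1.75, and the sterol exporter Abcg8 changed by -0.51. Fabp1 and the lipid droplet gene Plin2 (0.43), named after their values were seen, were the other members that rose. Of 15 tight junction genes, 0 rose, 8 fell and 7 did not pass, with 11 lower adjusted over the list alone (median -0.16, camera adjusted p = 6.09e-05, adjusted p = 0.142 with an estimated correlation). The claudins Cldn8, Cldn4 and Cldn23 changed by -1.999, -1.23 and -0.58, and F11r by -0.39. Smooth muscle genes had a median difference of -0.84 in the same samples.

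**Figure D2:**
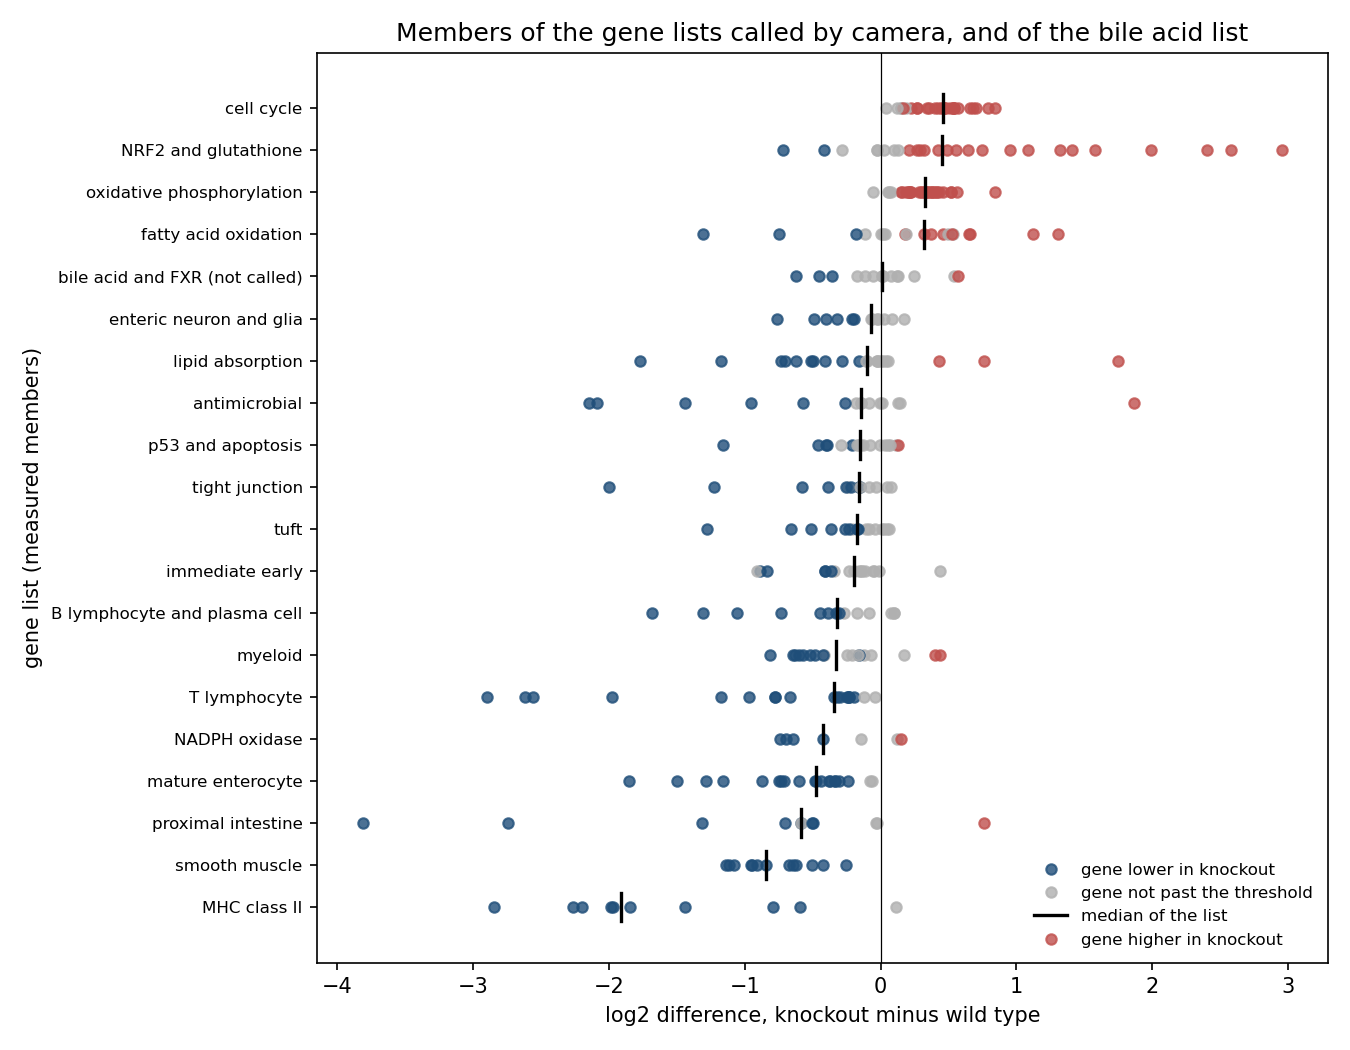
Log2 difference, knockout minus wild type, of each measured member of the 19 called gene lists and of the bile acid list, coloured by whether the gene was higher, lower or not past the threshold, with the list's median as a bar. Medians run from -1.91 for MHC class II to 0.46 for the cell cycle.

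Antigen presentation and lymphocyte genes were lower in the knockout. Of 10 genes of MHC class II presentation, 0 rose, 9 fell and 1 did not pass, while adjusted over the list alone 1 rose and 9 fell (median -1.91, camera adjusted p = 1.47e-07, adjusted p = 0.200 with an estimated correlation). H2-Aa changed by -1.97 (SE 0.16), H2-Ab1 by -2.20 (SE 0.20), H2-Eb1 by -1.85 (SE 0.16) and the peptide loading gene H2-DMa by -2.27 (SE 0.24). Knockout samples were more spread than wild type for these genes, with H2-Ab1 at 8.72 ± 0.53 against 10.92 ± 0.04 (SD, n = 4). Of 19 T lymphocyte genes, 0 rose, 17 fell and 2 did not pass, and 17 fell adjusted over the list alone (median -0.34, camera adjusted p = 2.5e-12, adjusted p = 0.102 with an estimated correlation). Gzma and the granzyme Gzmb changed by -2.90 and -2.62, the chemokine Ccl5 by -2.56 and the T cell receptor component Cd3g by -1.98. Of 14 B lymphocyte and plasma cell genes, 0 rose, 8 fell and 6 did not pass, with 10 lower adjusted over the list alone (median -0.32, camera adjusted p = 0.00304, adjusted p = 0.226 with an estimated correlation). The B lymphocyte genes Ms4a1, Cd79b and Cd22 changed by -1.69 (SE 0.37), -1.31 (SE 0.19) and -0.73 (SE 0.14), and the transcription factor Spib by -1.06. Of 18 myeloid genes, 2 rose, 9 fell and 7 did not pass, with 2 and 11 adjusted over the list alone (median -0.33, camera adjusted p = 0.000527, adjusted p = 0.36 with an estimated correlation). The cathepsin Ctss, Mpeg1 and Itgax changed by -0.82, -0.60 and -0.48, and the endotoxin coreceptor Cd14 rose by 0.44, as did Mrc1 by 0.40, named after its value was seen.

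Of 7 NADPH oxidase genes, 1 rose, 4 fell and 2 did not pass, the same 1 and 4 adjusted over the list alone (median -0.43, camera adjusted p = 0.0192, adjusted p = 0.151 with an estimated correlation). The phagocyte oxidase subunits Cybb and Cyba changed by -0.74 and -0.70, Rac2 by -0.65 and Ncf4 by -0.43. Noxo1, named after its value was seen, rose by 0.15. Of 15 antimicrobial genes, 1 rose, 6 fell and 8 did not pass, again 1 and 6 adjusted over the list alone (median -0.15, camera adjusted p = 0.02, adjusted p = 0.271 with an estimated correlation). The lectin Reg3a changed by -1.44, the serum amyloid Saa1 by -2.08 and the chemokine Cxcl16 by -0.57, and Il18 rose as given above. With the hybridization controls as a covariate, added after the data were seen, the antimicrobial list was not called (adjusted p = 0.0521).

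**Figure D3:**
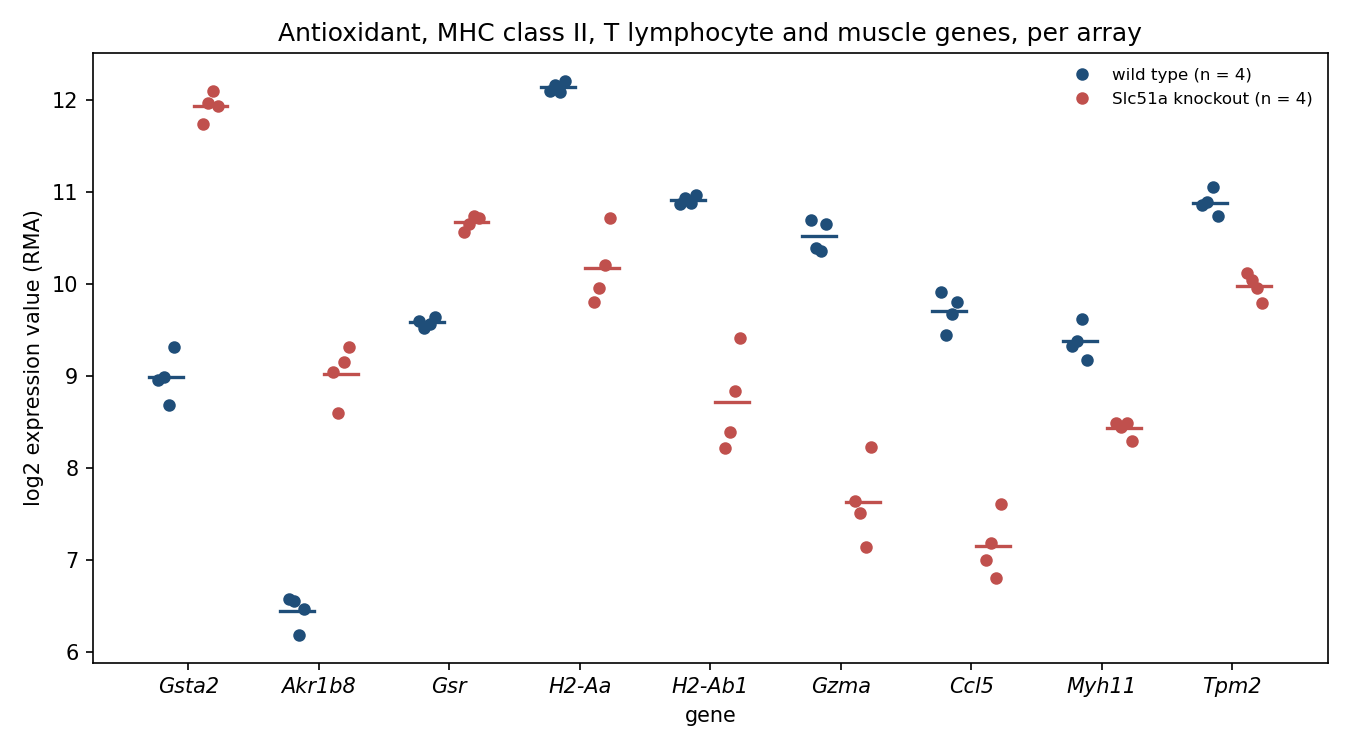
Log2 expression value (RMA) of 9 genes on each array, with wild type (n = 4) in blue and Slc51a knockout (n = 4) in red; points are arrays and lines are group means. Gsta2, Akr1b8 and Gsr lie higher in every knockout sample, and H2-Aa, H2-Ab1, Gzma, Ccl5, Myh11 and Tpm2 lower in every knockout sample.

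Markers of the muscle wall were lower in the knockout, and the enteric nerve marker Vip was too. Of 13 smooth muscle genes, 0 rose and 13 fell, as they did adjusted over the list alone (median -0.84, camera adjusted p = 7.17e-11, adjusted p = 0.151 with an estimated correlation). The desmin gene Des changed by -0.95, the smooth muscle myosin Myh11 by -0.94, the tropomyosin Tpm2 by -0.91 and the kinase Mylk by -0.63. Of 13 enteric neuron and glia genes, 0 rose, 6 fell and 7 did not pass, while 1 rose and 6 fell adjusted over the list alone (median -0.07, camera adjusted p = 0.0192, adjusted p = 0.156 with an estimated correlation). The median wild-type level of these genes was 4.30, below the median of all probe sets, 4.58, so the call rests largely on dim genes. The neuropeptide gene Vip changed by -0.76. Snap25 and Elavl4 passed too but lay below the median of all probe sets in both genotypes, so their expression is not shown. Of 18 fibroblast and matrix genes, 2 rose, 2 fell and 14 did not pass, with 2 and 2 adjusted over the list alone, and the list was not called (adjusted p = 0.818), its median being 0.01 and its mean -0.02. Vim changed by -0.44 and Loxl1 by 0.33, the latter call being lost without the 3 arrays (adjusted p = 0.0991).

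Of 16 tuft cell genes, 0 rose, 8 fell and 8 did not pass, with 9 lower adjusted over the list alone (median -0.17, camera adjusted p = 0.00151, adjusted p = 0.102 with an estimated correlation). Rgs13 changed by -1.28 and Alox5ap by -0.51. The succinate receptor Sucnr1 passed too but lay below the median of all probe sets in both genotypes, so its expression is not shown. Of 17 immediate early genes, 0 rose, 5 fell and 12 did not pass, with 6 lower adjusted over the list alone (median -0.19, camera adjusted p = 0.00103, adjusted p = 0.226 with an estimated correlation). The transcription factors Jun, Klf4 and Junb changed by -0.89, -0.83 and -0.41. Of 17 genes of the p53 response and apoptosis, 1 rose, 5 fell and 11 did not pass, with 1 and 6 adjusted over the list alone (median -0.15, camera adjusted p = 0.0147, adjusted p = 0.142 with an estimated correlation). Pmaip1, a BH3-only gene, changed by -1.16 and the survival gene Bcl2l1 by -0.40, a call lost with the mean of its probe sets (adjusted p = 0.0641). Zmat3, named after its value was seen, rose by 0.13.

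The other lists were not called with the preset correlation and all 8 arrays, though Paneth, endothelial, inflammation, interferon, stem cell, circadian and heat shock genes were in some alternatives. Of 15 circadian genes, 0 rose, 4 fell and 11 did not pass, with 4 lower adjusted over the list alone (camera adjusted p = 0.101), and the clock genes Cry1, Npas2 and Arntl changed by -1.70, -1.03 and -0.995. Of 9 heat shock genes, 5 rose, 2 fell and 2 did not pass, with 5 and 3 adjusted over the list alone (adjusted p = 0.101), and Hspa4l and Hspe1 rose by 0.71 and 0.68. Of 19 cholesterol synthesis genes, 7 rose, 3 fell and 9 did not pass, the same adjusted over the list alone (adjusted p = 0.587), with Mvd at 0.46 and Tm7sf2 at -0.29. Of 21 enteroendocrine genes, 5 rose, 3 fell and 13 did not pass, as adjusted over the list alone (adjusted p = 0.483). The gut hormones Cck and Pyy rose by 0.66 and 0.54 and the carboxypeptidase Cpe fell by 0.80. Of 17 goblet cell genes, 2 rose, 4 fell and 11 did not pass, with 3 and 4 adjusted over the list alone (adjusted p = 0.298), and Ccl6 and Clca1 changed by -0.71 and -0.40. Of 6 Paneth cell genes, 0 rose, 2 fell and 4 did not pass, with 3 lower adjusted over the list alone (adjusted p = 0.0544), Nupr1 at -0.50 and Defa21 at -0.34. Of 16 stem cell genes, 1 rose, 3 fell and 12 did not pass, with 1 and 2 adjusted over the list alone (adjusted p = 0.0906). Lrig1 rose by 0.24, a call lost without the 3 arrays (adjusted p = 0.0623). Rnf43, Lgr5 and Olfm4 changed by -0.25, -0.31 and -0.18, and without the 3 arrays 1 gene of the list was called lower. Of 16 interferon genes, 1 rose, 4 fell and 11 did not pass, the same adjusted over the list alone (adjusted p = 0.0769), with Gbp2 at -1.54 and Cxcl10 at -0.71. Of 19 inflammation genes, 0 rose, 4 fell and 15 did not pass, with 3 lower adjusted over the list alone (adjusted p = 0.0877), Ccl20 at -0.80 and Icam1 at -0.44.

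Of 21 genes of endoplasmic reticulum stress, 3 rose, 4 fell and 14 did not pass, with 4 and 4 adjusted over the list alone (adjusted p = 0.438), Asns at 0.74 and Dnajb9 at -0.83. Of 13 endothelial genes, 1 rose, 3 fell and 9 did not pass, with 1 and 6 adjusted over the list alone (adjusted p = 0.0671), Lyve1 at 0.41 and Kdr at -0.32. Of 9 adipocyte genes, 2 rose, 1 fell and 6 did not pass, as adjusted over the list alone (adjusted p = 0.958), with a median of -0.004 and a mean of 0.03 and Scd1 at 0.72. Of 12 pancreatic acinar genes, 0 rose, 1 fell and 11 did not pass, as adjusted over the list alone (adjusted p = 0.854), with a median of 0.05 and a mean of -0.05, and the colipase gene Clps fell by 1.06.

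In all, 19 of 35 lists were called by camera with its preset correlation, 4 higher and 15 lower. With an estimated correlation 0 were called, the smallest adjusted p being 0.102, and fry, which does not compare a list with other genes, called 24, so the list calls depend on the test used. The hybridization controls were at 8.57 ± 0.31 (SD, n = 4) in wild type and 8.34 ± 0.20 in the knockout (2-sided exact permutation p = 0.229, smallest possible 0.0286), and the 3' minus 5' signal of Gapdh differed by -0.12 (exact p = 0.0571) and that of Actb by 0.03 (exact p = 0.314).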

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

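Of the tests in this part, those of the Tfrc probe sets and of the other windows and of the neighbours without Tfrc were chosen only after the result was seen.

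Single samples that lay far from the other 3 of their genotype were found in 13 of 380 groups of 4 values, 3.42%, where chance gives about 1 in 20. In wild type replicate 2, Mpeg1 was lowest at 7.98 against 8.40 to 8.48 in the others, Cxcl10 at 5.33, Gbp2 at 7.25 and Clps at 10.19, and Adipor2 was highest at 9.82. The hybridization controls of that array were also lowest, at 8.11 against 8.69 to 8.78. In wild type replicate 3, Cpt2 was lowest at 9.56, Jun highest at 9.43, and the mean of the cell cycle list lowest at 7.55. Rnf43 was lowest in wild type replicate 1 at 5.28, and Atf4 in wild type replicate 4 at 9.72. In the knockout, Cyp3a25 was lowest in replicate 1 at 7.78 against 8.88 to 8.98, and Mpeg1 highest in replicate 3 at 7.93.

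Among the 16139 probe sets with no or several symbols, which entered no comparison, 1003 were higher and 1171 lower in the knockout.

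The transferrin receptor control probe sets, also outside the comparison, were higher in the knockout by 0.54, 0.64 and 0.66, at 3.35 to 3.76 in wild type and 3.99 to 4.30 in the knockout, below the median of all probe sets. Tfrc itself, the fourth nearest tested gene to Slc51a and named after its value was seen, rose by 1.39 (SE 0.08, limma adjusted p = 1.27e-06). A probe set that misreads Tfrc is argued against, since all 3 Tfrc probe sets rose, by at least 0.78; the 3 controls, the lowest at 0.54, add little at their level. A flanking chromosome segment from another strain stays open: 4 of the 50 tested genes nearest Slc51a changed at least 1.5-fold against 4.81% of other genes (one-sided Fisher's exact p = 0.22). That count includes Tfrc, which prompted the test, and without it 3 of 49 did (exact p = 0.422). Windows of 10, 25 and 100 genes, tried after the values were seen, gave exact p of 0.0666, 0.323 and 0.200 without Tfrc. With Tfrc the window of 10 held 3 such genes (exact p = 0.0104, 0.0415 adjusted over the windows). The genes ranked 1 and 2 by distance, named after their values were seen, were among them, Zdhhc19 at 0.73 (SE 0.11) and Pcyt1a at -0.83 (SE 0.07). A response of Tfrc to the missing transporter was not tested and stays open too.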

How the results depend on the processing

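The fits without the 3 arrays with the lowest hybridization controls and with these controls as a covariate were chosen only after the data were seen. The counts of changed genes stayed within 1.5 times of 5134 (2924 higher, 2210 lower) in the other settings, for example 4269 with the unmoderated equal-variance test and 5557 genes with all probe sets. Exceptions were 1446 lower genes at an adjusted p under 0.01, 825 genes (351 higher, 474 lower) with a fold of at least 1.5, and 1414 lower genes without the 3 arrays, where fewer genes are expected from stricter rules and fewer arrays. Leaving out 1 array gave 4366 to 4945 genes, 2493 to 2853 higher and 1873 to 2100 lower, Slc51a at -6.78 to -6.72, and 18 to 22 lists. Of 149 named genes other than Slc51a, 2 to 8 lost their call on leaving out 1 array, 14 without the 3 arrays, 8 with the covariate and 0 to 5 in the other settings that kept them; the filter on dim genes left 142, of which 0 lost it. Higher genes were 57.0% of those changed, 48.7% with cyclic loess (2509 against 2646 lower) and 62.7% with median centring. The 3 arrays left 3321 genes called in the same direction and 0 in opposite directions.

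With an estimated correlation 0 lists were called instead of 19, and fry called 24. Calls were lost even where the estimated correlation lay below the preset 0.01. It was 0.0097 for tuft cells, 0.0077 for NADPH oxidase and -0.018 for p53 and apoptosis. A correlation above the preset therefore does not account for every lost call, and other causes were not tested. Lists that were called lower only in some alternatives, besides the xenobiotic list, were Paneth (without dim genes, adjusted p = 0.0357; median centring, 0.0450; mean of probe sets, 0.0474; without wild type 2, knockout 2 or knockout 3, 0.00437, 0.0383 and 0.0374; without the 3 arrays, 0.00369), endothelium (without wild type 1 or knockout 4, 0.0451 and 0.0452; without the 3 arrays, 0.0446; fry, 0.0101) and inflammation (without wild type 2, 0.0378; without the 3 arrays, 0.0217; fry, 0.00669). Others were interferon (without wild type 2 or knockout 1, 0.0295 and 0.0111), stem cells (without wild type 1, 0.0355) and circadian genes (without knockout 3, 0.0384; fry, 0.0196), and heat shock was called higher by fry (0.000122). The replicate block gave 5190 genes (2945 higher, 2245 lower), Slc51a at -6.75 and 20 lists, the xenobiotic list being the one gained (adjusted p = 0.0431). Deviations of same-numbered samples correlated at 0.235, -0.097, 0.077 and 0.159, and those of differently numbered samples at -0.146 to 0.195. No test compared them, so a pairing by number is neither shown nor excluded.

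Medians of uncalled lists whose tested direction turned were, for adipocyte genes, -0.012 without dim genes, 0.018 with median centring, -0.0041 with the replicate block and -0.096 to 0.034 on leaving out 1 array; for cholesterol synthesis, 0.0056 with quantile normalisation and -0.0071 with cyclic loess; for fibroblast genes, -0.012 to 0.033 on leaving out 1 array and 0.051 with the covariate; and for acinar genes, 0.035 to 0.0755 on leaving out 1 array, 0.081 without the 3 arrays and 0.033 with the covariate. Fabp6 turned to -0.030 with cyclic loess. The cause was not tested. Low signals near background limit what the arrays can show.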

Other observations

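Of the tests in this part, those of Cd74, of both sets of B lymphocyte genes, of the Actb and Gapdh signals and of the hypoxia targets without glycolytic enzymes were chosen only after the result was seen; the gene sets for interferon gamma, hypoxia, the villus tip and further muscle genes were written after the main results but before their own values were looked at.

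Beyond the fixed lists, interferon gamma responsive genes were lower in the knockout, 21 of 24 past the threshold (median -0.86, one-sided Fisher's exact p = 2.76e-16). Fisher's tests in this part and of the genes near Slc51a treat genes as independent, though genes of the same 8 samples can vary together. The fixed interferon list had an estimated correlation of 0.53. These p values do not measure replication across mice and may be too small. Examples, picked after their values were seen, were the MHC class I gene H2-T23 (-1.11), the proteasome subunit Psmb8 (-1.29), Nlrc5 (-1.56), Cxcl9 (-1.47) and Ido1 (-1.33). Of 24 targets of hypoxia-inducible factor, 12 were higher and 4 lower (median 0.36). Pkm (0.94), Pgk1 (0.80), Car9 (0.99) and Aldoa (0.61) were higher, and Vegfa (-1.26), Pfkfb3 (-0.91), Pfkfb4 (-0.55) and Hk2 (-0.49) were lower.

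For the fall of the MHC class II genes (median -1.91), an H2 haplotype from another strain is argued against, since Cd74, whose gene lies outside that complex, fell by 1.99 (SE 0.21) against a median of -1.97 for the H2 members. The 5 B lymphocyte and plasma cell genes with a wild-type mean above 6 had a median of -0.73 (SD 0.70), above the MHC median by more than their SD. That met the bound set against fewer of these cells. In the knockout, however, Ms4a1, Cd22 and Cd79b lay at 5.55, 6.02 and 6.09, against 8.72 for H2-Ab1. Falls nearer the floor may be understated, so the test does not decide whether fewer of these cells were the cause. Plasma cells also express Jchain (-0.18, SE 0.06) and Ighm (-0.09, SE 0.51) of the 5 genes. The test was therefore repeated without them after its value was seen, a choice that moved the median toward the MHC median. The 3 genes left had a median of -1.31 (SD 0.48), again above the MHC median by more than the SD. As 3 genes are under the minimum of 5, also set after the first value, fewer B lymphocyte follicles stay open. Across the knockout arrays the means of these 3 genes (5.22, 5.84, 6.16 and 6.33) and of the MHC genes (8.74, 8.92, 9.25 and 9.83) rose in the same order. In wild type they were at 6.60, 7.27, 7.42 and 7.24 and at 11.15, 11.21, 11.16 and 11.23, not in the same order. Wild type replicate 1 and knockout replicate 4 were close in the 3 genes (6.60 and 6.33) but not in the MHC genes (11.15 and 9.83). The order of the arrays therefore does not decide the question. Lower interferon gamma signalling may contribute, as 21 of 24 further responsive genes fell, and this stays open as a hypothesis.

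The smooth muscle genes had a median of -0.84. A difference in RNA degradation stays open: the 3' minus 5' signal differed by -0.12 for Gapdh (exact p = 0.0571) and by 0.03 for Actb (exact p = 0.314). The bound first set against it, opposite signs or a p at or above 0.05, was met but excludes nothing, since the Actb value lies within its spread (SD 0.05 and 0.02) and a p that misses 0.05 does not show equality. A smaller share of muscle wall in the knockout samples stays open too: of 20 further muscle genes 15 fell (median -0.39), and the 12 with a wild-type mean above 6 had a median of -0.49 (SD 0.20), lower than 0 but by less than the fixed list. The fibroblast list, with a median of 0.01 and 2 of 18 genes higher and 2 lower, did not fall as a group. A change within the muscle itself was not tested.

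Higher activity of hypoxia-inducible factor is a hypothesis for the rise of glycolytic enzymes and of Egln3 (1.26, named after its value was seen): 12 of 24 further targets rose, 50% against 17.1% of other genes (one-sided Fisher's exact p = 0.000216), and 4 fell, but 7 of the 24 are glycolytic enzymes themselves. The 12 of 24 met the bound of at least 50% set beforehand. That bound was not written for the set without glycolytic enzymes, which was chosen afterwards. In that set 7 of 17 rose, 41.2%, and 3 fell (median 0.15, exact p = 0.0168). As the set that met the bound holds enzymes whose rise was to be explained, the hypothesis stays open. Less of a villus-tip programme was a hypothesis for the fall of Ada, Nt5e and Slc28a2, but 4 of 11 villus-tip genes fell (median -0.16), 36.4% against 12.9% of other genes (exact p = 0.0434), which lies between the bounds set beforehand, so it stays open.

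In the 35 splits of the 8 arrays into 4 and 4, the real one gave 5134 changed genes, 2924 higher and 2210 lower. The highest other gave 0 for each count, so 1 of 35 was as large. That is the smallest share that 35 splits can give. All other splits mix the genotypes, so the genotype difference itself widens the spread within their groups. Their counts of 0 are therefore no measure of chance, and these splits cannot exclude it. For the 19 lists called, 5 of 35 splits gave as many and the highest other gave 22, which met the bound set beforehand for chance. The 4 other splits with as many were among the 16 that put 3 arrays of a genotype together. Part of the genotype difference remains between the sides of those 16, so their counts are no measure of chance either. In the 18 splits that put 2 arrays of each genotype on both sides the highest was 7, and 0 gave as many. The genotype difference widens the spread in these too, so the splits neither show nor exclude chance for the lists.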
